A study of Homo sapiens with 62 samples.

How the data were processed

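ATAC-seq inserts sequencing adapters into accessible DNA with the transposase Tn5, so that reads pile up where chromatin is open. It was carried out on nuclei of GM12878, an established human lymphoblastoid cell line, at 7 concentrations of Tn5 from 0.2X to 5X, where 1X is the amount of enzyme that the labels name as the unit. Per the labels, nuclei came from independent cultures, 6 for an experiment with a fixed 16 cycles of PCR (PCR-constant) and 3 for an experiment in which the number of cycles was chosen for each library by qPCR (PCR-variable). The 62 samples form 14 groups, 42 libraries in PCR-constant and 20 in PCR-variable. The 0.5X library of the third PCR-variable isolation was not analysed here. Each PCR-variable library was sequenced on a run with low and on a run with high cluster density, which gave 82 count files and 82 peak lists in all. In PCR-variable the cycles fell with the enzyme, from 18 at 0.2X through 16 at 0.5X, 15 to 16 at 0.66X and 1X and 14 to 15 at 1.5X and 2X to 12 to 13 at 5X (Pearson r = −0.963 between cycles and log2 Tn5 over 20 libraries).

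The authors' files are in build hg19 and the tools the authors used, per the submitters' processing notes, were CASAVA, bcl2fastq 2.17.1.14, BWA 0.7.15-r1140, SAMtools, Picard, MACS2 2.1.1.20160309 and bedtools 2.27.1, named without their roles or order. The deposited count files hold whole-number read counts per master peak, not normalized, with the same master peaks in every file of one experiment. How the master peaks were made, which duplicate or low-quality reads were removed and whether a fragment counts once or more is not given in the sources used here. Even counts made up 57.09% of all counts from 2 to 7 in PCR-constant, 57.12% in the low run and 58.87% in the high run. The deposited peak lists are in the layout MACS2 writes for broad peaks, called per library in PCR-constant and per library and run in PCR-variable, judging from the names of the peaks. They give the authors' fold enrichment of each peak over local background, a ratio within one library, and the authors' −log10 q-value. Fold enrichment was used only to describe each list by its median and to describe sites, and the −log10 q only to filter peaks at 5 or more.

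PCR-constant had 70658 master peaks on 22 chromosomes, 200 to 4464 bp wide (median 521 bp) and covering 46.8 Mb. PCR-variable had 65585, 200 to 4434 bp wide (median 564 bp) and covering 45.92 Mb. Reads counted in master peaks numbered 867696 to 12018492 per library in PCR-constant (median 3779733.5), 1499645 to 13769300 in the low run (median 5623589.5) and 1652166 to 16723791 in the high run (median 6793353.5). These totals are the depth behind the counts, and they rose with Tn5. Coordinates are 1-based positions in hg19. No gene annotation of that build was used here, so peaks are named by position, and the planned share of reads near transcription start sites, the class of peaks near start sites and the gene list tests were not run. GC content was not tested, because no genome sequence was used.

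Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) by the quasi-likelihood test (estimateDisp, glmQLFit, glmQLFTest), after filterByExpr and with TMM factors. The p-values were adjusted by Benjamini-Hochberg over all peaks tested and a threshold of 0.05 was applied. For each experiment the tested coefficient was the slope on log2 Tn5, in log2 reads per doubling of enzyme, over all libraries (the low run in PCR-variable). In PCR-constant, 0.2X, 0.66X, 1.5X and 5X were also each compared with 1X over the 12 libraries involved. The high run was compared with the low run within libraries, each library being a block. The SE of a log2 value was taken from the value and its test statistic. CPM values give the reads of a peak relative to all reads of the library in master peaks. The rule for named peaks took peaks past the threshold with a mean of at least 50 reads and the same sign in every isolation (every library for the runs). It took the 10 largest rises and 10 largest falls for the PCR-constant slope, the 3 largest each way for every other count comparison, and the 5 master peaks with the highest mean CPM in PCR-constant. A few peaks with fewer reads that changed more are named beside them and were chosen after their values were seen. This rule, the tests and the alternatives not marked as added later were fixed before the data were examined.

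Values per library were fitted on log2 Tn5 within each isolation, and the mean slope was tested over isolations by a two-sided exact sign-flip permutation test. The smallest p it allows is 0.03125 with 6 isolations and 0.25 with 3, so the sign-flip test could not reach 0.05 over the 3 PCR-variable isolations. A permutation test with 100000 permutations of the concentrations within isolations, whose smallest p is 1e-05, was run beside it. These values were the number of peaks called, their median width, the Mb they covered, their median fold enrichment, the log2 number of reads in master peaks and the share of reads in the top 10% of master peaks by mean CPM. The top 10% was set by mean CPM over all libraries in PCR-constant and over the low run in PCR-variable. The peaks called at 1X were matched to those at the other concentrations of the same isolation by an overlap of at least 1 bp (bedtools 2.31.1). Master peaks of both experiments were matched by a reciprocal overlap of at least 50%. For quartiles of master peaks by width and by mean CPM, and, added after seeing the data, for classes by the number of other master peaks within 50 kb, the median slope per isolation was compared between the top and the bottom class. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

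The slopes within isolations were first computed by least squares on log2 CPM with a prior count of 2, and the class medians from them had been seen before the method was changed to a negative binomial fit per isolation. The change was made because those medians differed from the slopes of the edgeR fit over all libraries and because low counts can bias slopes on the log scale. On simulated unchanged peaks the median slope of the lowest and the highest CPM quartile was 0.0147 and 0.0009 by the first method and −0.0053 and −0.0005 by the second. That bias is smaller than the shift of the mean CPM contrast of PCR-constant between the methods in the real data, so it could account for part of it at most. The width contrast and PCR-variable were not simulated in this way. The contrasts between classes of width, mean CPM and neighbours are therefore printed by both methods. Class medians, chromosome medians and some contrasts within quartiles are printed by the second alone.

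The tests were checked on simulated counts drawn from the means and library sizes of the real libraries, with 200 peaks changed by known amounts. In the PCR-constant slope (67352 peaks tested) 16.4% of the changed peaks were called at a slope of 0.1, 66.7% at 0.2 and 86.4% at 0.3. In the PCR-variable slope (65283 peaks) these shares were 11.9%, 56.7% and 75.8%. At log2 changes of 0.5, 0.8 and 1.2 the shares were 9.2%, 41.5% and 77.4% for 0.2X against 1X (49952 peaks) and 13.8%, 43.5% and 74.2% for 0.66X (54801 peaks). They were 25.4%, 63.1% and 73.8% for 1.5X (63142 peaks) and 26.9%, 68.2% and 90.9% for 5X (66109 peaks). For the runs (63450 peaks), changes of 0.1, 0.2 and 0.3 were called in 1.5%, 31.3% and 37.9%.

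The replicate number in the labels stands for a nuclear isolation, so libraries with the same number share a culture. Deviations from the group means correlated between libraries of the same isolation with a median r of 0.0895 in PCR-constant (48 of 126 pairs over 0.1). There 26 of 42 libraries had their highest mean correlation, over libraries of other concentrations, with their own isolation. In PCR-variable the median r was 0.0157 (2 of 57 pairs over 0.1) and 17 of 20 libraries had their highest mean correlation with their own isolation. Counts were fitted without isolation as a block and the block was an alternative. Isolations 1 to 3 and 4 to 6 of PCR-constant formed separate sets in these deviations, compared between libraries of different concentrations (mean r of 0.056 to 0.082 in 6 pairs of isolations within a set and −0.092 to −0.06 in 9 pairs between sets). For the main comparisons values for each set are therefore printed beside pooled ones. Slopes of named peaks, contrasts within quartiles, chromosome medians and the depth estimate are printed pooled only. Between 2 libraries of 1 group the chi-square per degree of freedom was 1.895 to 4.821 over 105 pairs in PCR-constant. It was 1.917 to 2.173 over 19 pairs in PCR-variable, in both cases for master peaks with at least 20 reads in the pair. Independent reads give a value near 1, but the 2 runs of 1 PCR-variable library reached up to 1.896. The closest pairs therefore lay no further apart than 2 runs of 1 library can. Other splits of the libraries exchanged concentrations within isolations (32 splits for each comparison with 1X, 40 draws for each slope) or runs within libraries (22 draws).

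The alternatives fixed in advance were DESeq2 1.42.0, scaling to total reads, loess offsets with a span of 0.3, no filter, a filter of at least 50 reads on average, thinning every library to the smallest total, the isolation as a block, leaving out the 0.2X or the 5X libraries, and leaving out each PCR-variable isolation. For PCR-variable they were also the high run, the sum of both runs and the number of PCR cycles as a covariate. For peak lists they were a −log10 q of at least 5, a reciprocal overlap of 50% and the top 5% in place of the top 10%. Added after seeing the data were each set of 3 PCR-constant isolations alone, the fit without the library with the fewest reads, the classes by neighbours, the first slope method, the class contrasts within quartiles of width or mean CPM, the estimate of depth effects without each isolation and the high run with a block.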

Results

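Accessible chromatin was measured by ATAC-seq in GM12878 lymphoblastoid cells at 7 Tn5 concentrations. PCR-constant held 42 libraries from 6 nuclear isolations, all amplified for 16 cycles, and PCR-variable 20 libraries from 3 further isolations with 12 to 18 cycles, each sequenced in a low and a high cluster density run. Reads in master peaks had a positive slope on Tn5 in every isolation, with means from 1668040 ± 673555 at 0.2X through 3964960 ± 1059680 at 1X to 8672840 ± 2686070 at 5X in PCR-constant (mean ± SD, n = 6). In the low run of PCR-variable the means went from 1671070 ± 217417 at 0.2X through 5410810 ± 531088 at 1X to 11328000 ± 2182280 at 5X (n = 3). Depth therefore changed with the concentration in every comparison between concentrations that follows. The slope of log2 reads was 0.53 ± 0.15 per doubling of Tn5 in PCR-constant (mean ± SD over 6 isolations, two-sided exact sign-flip permutation p = 0.03125, the smallest possible). It was 0.63 in isolations 1 to 3, 0.43 in isolations 4 to 6 and 0.62 ± 0.083 in PCR-variable (exact permutation p = 0.25, the smallest possible with n = 3, and p = 1e-05 when concentrations were permuted within isolations).

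The first question was how the peaks that a library yields depend on the amount of transposase. More peaks were called at higher Tn5. In PCR-constant the number rose from 39965 ± 10002 at 0.2X and 54207 ± 10734 at 0.5X to 69259 ± 12145 at 1X, 82223 ± 4474 at 2X and 93676 ± 9062 at 5X (mean ± SD, n = 6). This was a gain of 11886 ± 3238 peaks per doubling, positive in 6 of 6 isolations (two-sided exact permutation p = 0.03125). The gain was 13815 in isolations 1 to 3 and 9958 in isolations 4 to 6. In the low run of PCR-variable the number rose from 38787 ± 7804 at 0.2X to 60348 ± 3474 at 1X and 85938 ± 2010 at 5X (n = 3), or 10504 ± 1558 per doubling in 3 of 3 isolations (exact permutation p = 0.25). Permuting the concentrations within isolations gave p = 1e-05 in both experiments, the smallest these permutations can give. The slope of the log2 number of peaks differed by −0.023 between PCR-variable (0.25 ± 0.055, n = 3) and PCR-constant (0.28 ± 0.092, n = 6), a difference within the spread between isolations (two-sided exact permutation p = 0.69). The experiments differed in cultures, sequencing and master peaks as well as in PCR cycles. Comparisons between them, here and below, cannot tell these apart.

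The genome covered by peaks grew by 6.39 ± 2.02 Mb per doubling in PCR-constant (exact permutation p = 0.03125, n = 6), by 7.59 Mb in isolations 1 to 3 and 5.20 Mb in isolations 4 to 6. In PCR-variable the slope was 7.19 ± 0.883 Mb (exact permutation p = 0.25, n = 3). Coverage at 0.2X, 1X and 5X was 18.8 ± 5.95, 33.6 ± 6.40 and 47.8 ± 6.10 Mb in PCR-constant (n = 6). Median fold enrichment rose by 0.241 ± 0.071 per doubling in PCR-constant (exact permutation p = 0.03125, n = 6), by 0.282 in isolations 1 to 3 and 0.201 in isolations 4 to 6. In PCR-variable its slope was 0.182 ± 0.0572 (exact permutation p = 0.25, n = 3). Among peaks with −log10 q of at least 5 the slopes in PCR-constant and PCR-variable were 0.142 and 0.0111. No change of median peak width with Tn5 was detected in PCR-constant, with a slope of 0.417 ± 8.49 bp per doubling (exact permutation p = 0.875, n = 6). Its direction differed between isolations 1 to 3 (6.37 bp) and 4 to 6 (−5.53 bp), and among peaks with −log10 q of at least 5 the width fell by 18.9 bp per doubling (exact permutation p = 0.03125, n = 6). At 0.2X isolations 1 and 3 had narrow lists, with median widths of 307 and 283 bp. Without the 0.2X libraries the slope was −3.91 bp, positive in 1 of 6 isolations (exact permutation p = 0.09375). In PCR-variable the median width went from 348 ± 32.5 bp at 0.2X to 431 ± 7.57 bp at 5X (18.4 ± 5.69 bp per doubling, exact permutation p = 0.25, n = 3). With the stricter q the PCR-variable slope was 7.96 bp. A permutation of the concentrations within the 3 PCR-variable isolations gave p = 1e-05 for the Mb covered and for the median width and p = 7e-05 for the median fold enrichment. The difference of 18.0 bp between the experiments had a two-sided exact permutation p = 0.0238 over 84 splits and 0.107 when adjusted over 9 such tests.

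**Figure D1:**
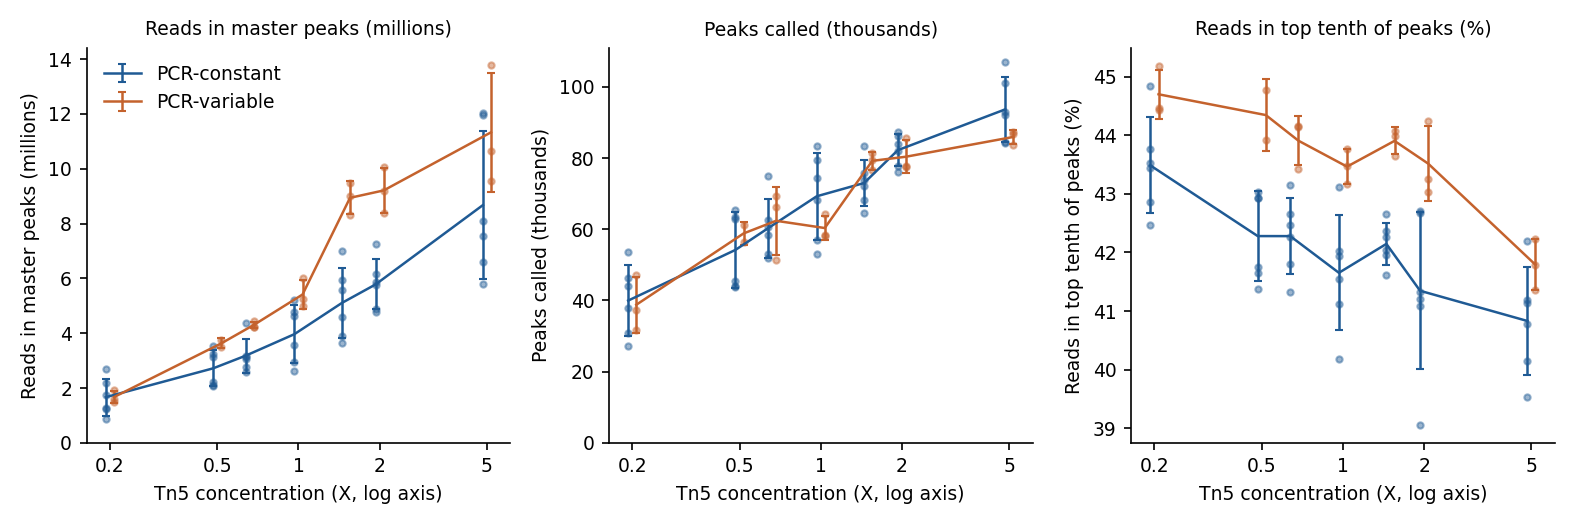
Reads in master peaks, peaks called and the percent of reads in the top 10% of master peaks, per library, against Tn5 concentration (X, log axis), with points for libraries and lines and bars for the mean ± SD of each group of PCR-constant and of the low run of PCR-variable. The number of peaks called rose from 39965 at 0.2X to 93676 at 5X on average in PCR-constant and from 38787 to 85938 in the low run of PCR-variable.

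The share of 1X peaks found again in the same isolation rose with the concentration of the other library. Of the peaks called at 1X in PCR-constant, 48.7 ± 5.93% were overlapped by a peak at 0.2X, 67.1 ± 4.49% at 0.5X, 72.0 ± 5.37% at 0.66X, 82.2 ± 5.07% at 1.5X, 85.9 ± 4.94% at 2X and 89.8 ± 5.02% at 5X (mean ± SD, n = 6). The share at 5X exceeded that at 0.2X by 41.1 ± 10.7 percentage points, in 6 of 6 isolations (two-sided exact permutation p = 0.03125). The difference was 48.7 points in isolations 1 to 3 and 33.5 in isolations 4 to 6. With peaks of −log10 q of at least 5 it was 70.8 points. The lists differed in length, so these shares carry the number of peaks with them.

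The share of reads in the top 10% of master peaks by mean CPM fell with Tn5. In PCR-constant it was 43.5 ± 0.819% at 0.2X, 41.7 ± 0.983% at 1X and 40.8 ± 0.916% at 5X (n = 6), and it fell by 0.532 ± 0.398 points per doubling in 6 of 6 isolations (two-sided exact permutation p = 0.03125). The slope was −0.875 in isolations 1 to 3 and −0.190 in isolations 4 to 6. Without the 5X libraries it was −0.557 (exact permutation p = 0.125, n = 6) and without the 0.2X libraries −0.439 (exact permutation p = 0.0938, n = 6). In PCR-variable the share was 44.7 ± 0.423% at 0.2X and 41.8 ± 0.437% at 5X, with a slope of −0.553 ± 0.114 in 3 of 3 isolations (exact permutation p = 0.25, and p = 1e-05 when concentrations were permuted within isolations) that was −0.337 without the 5X libraries. The top 10% was chosen by mean CPM over these same libraries, each with equal weight. Libraries with few reads have the noisiest CPM, so this choice can favor a higher share at low Tn5. How much of the fall it makes up was not tested.

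Relative accessibility of single master peaks was then followed over the whole series in PCR-constant. Among called peaks with a mean of at least 50 reads and the same sign in every isolation, the steepest fall was at 2:117509661-117509945, a narrow peak of 285 bp, from 80.0 ± 48.8 CPM at 0.2X through 27.9 ± 7.13 at 1X to 12.7 ± 3.11 at 5X (mean ± SD, n = 6; slope −0.53 log2 per doubling, SE 0.033, edgeR adjusted p = 3.4e-30). The broad peak at 15:22460959-22462563 (1605 bp) fell from 335.8 ± 36.1 through 211.9 ± 30.4 to 107.8 ± 7.01 CPM (slope −0.34, SE 0.016, edgeR adjusted p = 2.2e-43). The peak at 14:107119773-107120453 fell from 64.3 ± 30.4 to 15.1 ± 2.19 CPM (slope −0.42) and that at 12:562089-562900 from 39.4 ± 12.7 to 10.1 ± 1.28 CPM (slope −0.41). The steepest rise by the same rule was at 19:14696001-14696341, from 7.65 ± 2.86 CPM at 0.2X through 16.1 ± 4.17 at 1X to 25.3 ± 2.83 at 5X (slope 0.325, SE 0.032, edgeR adjusted p = 4.4e-16). The peaks at 9:126558315-126558742 and 12:919742-920178 rose from 5.62 ± 2.66 to 18.5 ± 2.63 and from 5.23 ± 1.55 to 15.6 ± 1.28 CPM (slopes 0.31 and 0.30). Below 50 reads on average, 6 called peaks had a steeper fitted fall and 38 a steeper rise. The steepest of these falls, at 1:77436834-77437201, had a slope of −1.07 (SE 0.052, edgeR adjusted p = 3.5e-41) and a mean of 44.4 reads.

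The other peaks among the 10 largest falls were at 2:186603555-186604009, 7:126893629-126894312, 2:72364456-72365093, 6:78078250-78079055, 7:122525704-122527052 and 1:84326099-84326951, with slopes from −0.35 to −0.31. Of these, 6:78078250-78079055 went from 49.2 ± 16.5 to 19.6 ± 0.871 CPM between 0.2X and 5X. The other peaks among the 10 largest rises were at 2:103280890-103281294, 12:31899701-31900003, 9:126972975-126973371, 4:38818088-38818402, 19:7183067-7183650, 16:10060561-10061050 and 14:77411643-77412023, with slopes from 0.26 to 0.29. The peak at 2:103280890-103281294 went from 15.1 ± 5.95 to 30.6 ± 4.82 CPM. Among the 5 peaks with the highest mean CPM, 3:119813124-119814734 fell from 327.7 ± 20.4 CPM at 0.2X to 215.9 ± 17.7 at 5X (slope −0.13) and 5:151150590-151151700 from 309.8 ± 17.3 to 210.3 ± 11.9 (slope −0.12). The slopes at 19:42772311-42773483 (−0.081) and 14:105956088-105957769 (−0.084) passed the edgeR threshold but not with loess offsets (−0.0070 and −0.013). The peak with the highest mean CPM, 12:6960400-6962337, had a slope of −0.033 (edgeR adjusted p = 0.031), which reversed to 0.044 with loess offsets.

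Of 68285 master peaks tested in PCR-constant, 18454 changed with Tn5, 8507 upwards and 9947 downwards (edgeR quasi-likelihood test, adjusted p under 0.05). Scaling to total reads turned this majority, with 9954 upwards and 8973 downwards. Of the 18454 peaks called with TMM factors, 9291 had a mean of at least 50 reads, and 6532 of the 9291 had the same sign in each of the 6 isolations, 3298 upwards and 3234 downwards. With every library thinned to the smallest total 5985 of 33530 peaks tested were called (17.85%, against 27.02% before), and without the 5X libraries 8491 of 66376. Isolations 1 to 3 gave 6824 calls and isolations 4 to 6 gave 13876, of which 3639 were called in both sets, 3619 with the same sign and 20 with opposite signs. Over the 65947 peaks tested in both sets the slopes correlated with r = 0.579 (Spearman's rho = 0.57), across peaks, which are not independent replicates.

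**Figure D2:**
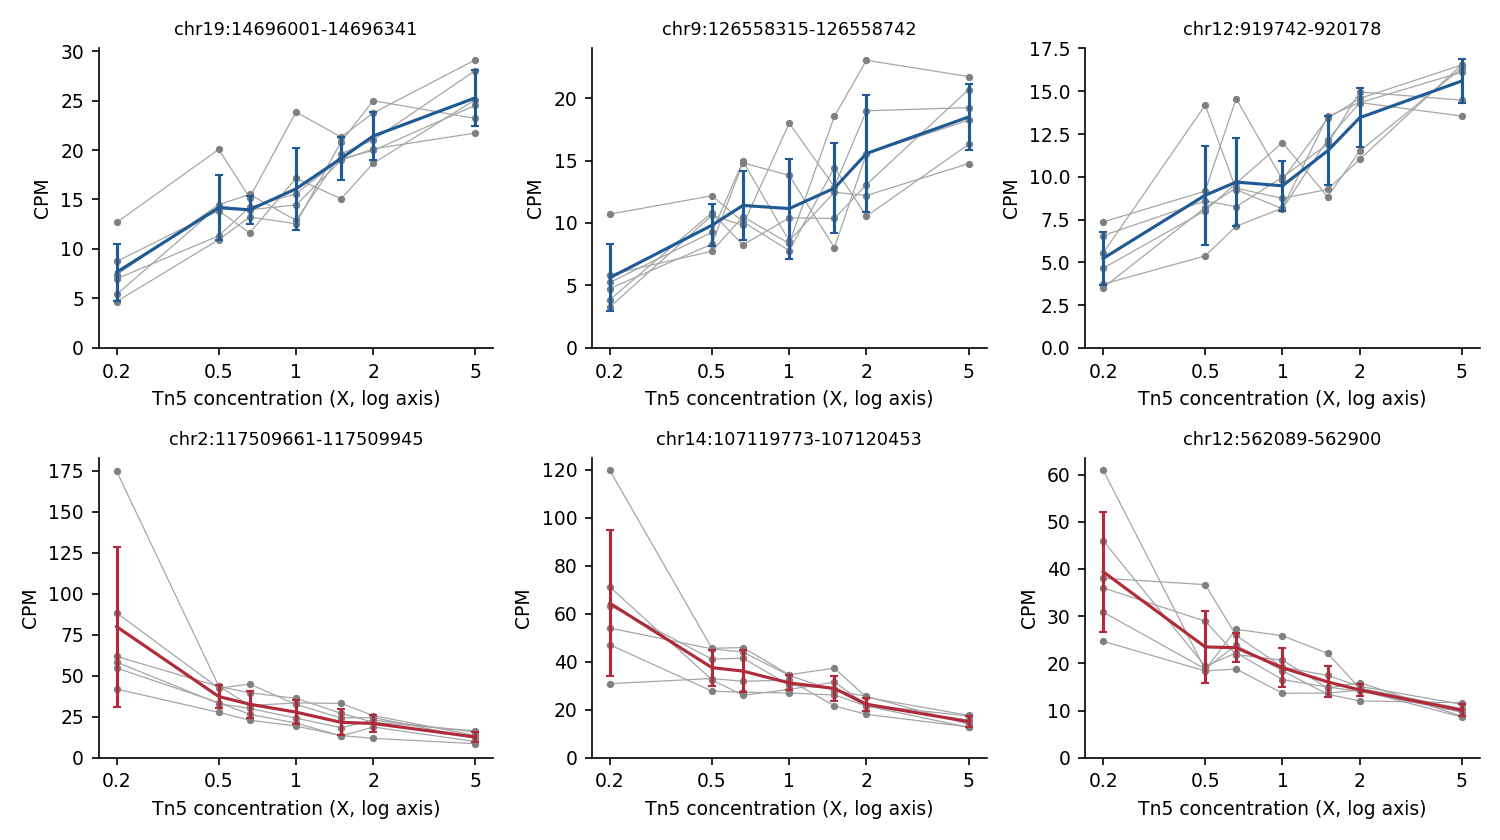
CPM of the 3 named master peaks with the largest rises (blue) and the 3 with the largest falls (red) in PCR-constant against Tn5 concentration (X, log axis), with grey points and lines for the 6 isolations and colored lines and bars for the mean ± SD. The peak at 2:117509661-117509945 went from a mean of 80.0 CPM at 0.2X to 12.7 at 5X and that at 19:14696001-14696341 from 7.65 to 25.3.

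Single concentrations were set against 1X to find the size of step at which peaks could be told apart. At 0.2X the narrow peak 1:77436834-77437201 was higher than at 1X by 2.55 log2 (73.5 ± 69.4 against 11.8 ± 4.16 CPM, n = 6, SE 0.23, edgeR adjusted p = 4.4e-14). The level of the matching PCR-variable peak, 1:77436816-77437201, differed between runs of the same libraries, with 50.4 ± 10.6 CPM in the low and 105.1 ± 30.5 in the high run at 0.2X and 8.84 ± 1.28 and 16.9 ± 1.99 at 1X (n = 3). The peaks at 2:117509661-117509945 and 12:562089-562900 were higher by 1.44 and 1.03. Among peaks with at least 50 reads on average and the same sign in every isolation, the largest decreases were at 2:65280345-65280734 (−0.88, from 25.3 ± 3.83 to 13.0 ± 4.41 CPM), 22:40357370-40357822 (−0.88) and 8:128671182-128671599 (−0.86). In isolations 1 to 3 alone these 3 decreases (−1.17, −0.89 and −1.10) and the rise at 12:562089-562900 (1.01) were of similar or larger size but did not pass the threshold. Those at 2:65280345-65280734 (−0.75) and 8:128671182-128671599 (−0.76) did not in isolations 4 to 6 alone either. Of 52171 peaks tested, 595 differed, 468 higher and 127 lower at 0.2X. The share of higher calls was 78.66% with TMM factors, 62.2% with total reads (500 calls) and 60.36% with loess offsets (338 calls). DESeq2 called 1114 peaks, thinned libraries gave 172 calls among 24181 peaks tested, and isolations 1 to 3 and 4 to 6 alone gave 39 and 191.

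At 5X, by the same rule, the peaks at 13:41556898-41557206 (5.75 ± 1.71 to 12.1 ± 2.78 CPM, 1.04 log2), 17:4915262-4915573 (5.96 ± 1.75 to 12.0 ± 3.54 CPM, 1.02) and 9:6051612-6051892 (4.76 ± 1.93 to 9.90 ± 1.50 CPM, 1.00) rose most against 1X (n = 6). In isolations 1 to 3 alone the first and the last of these had similar log2 changes (0.94 and 1.07) but did not pass the threshold (edgeR adjusted p = 0.065 and 0.051). The largest falls by this rule were at 2:186603555-186604009 (22.6 ± 5.01 to 9.66 ± 1.28 CPM, −1.19, SE 0.14, edgeR adjusted p = 1.9e-09), 2:117509661-117509945 (−1.13) and 19:18335218-18335737 (21.96 ± 4.05 to 10.2 ± 2.33 CPM, −1.09). Of called peaks with fewer than 50 reads on average, 156 fell further, the most at 1:77436834-77437201 (11.8 ± 4.16 to 1.66 ± 0.809 CPM, −2.84, SE 0.25, mean of 29.1 reads). Of 67005 peaks tested, 5475 differed at 5X, 2235 higher and 3240 lower. Thinned libraries gave 2758 calls among 52013 peaks tested, and isolations 1 to 3 and 4 to 6 alone gave 1130 and 2599.

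At 1.5X a single peak of 64560 tested differed from 1X, 5:21459335-21459902, which fell from 35.4 ± 4.38 to 21.0 ± 2.62 CPM (−0.75 log2, SE 0.11, edgeR adjusted p = 0.00017, n = 6). A raw p under 0.05 was reached by 3622 peaks. Chance alone gives a share of about 0.05 of the peaks tested in this and every such count. In isolations 1 to 3 and 4 to 6 alone edgeR called 0 peaks, with 2860 and 4386 at a raw p under 0.05, and the log2 change at 5:21459335-21459902 was −0.76 and −0.75. At 0.66X edgeR called 0 of 56765 peaks (2216 at a raw p under 0.05) and DESeq2 called 0 (2028 at a raw p under 0.05). In simulated libraries 13.8% of changes of 0.5 log2, 43.5% of changes of 0.8 and 74.2% of changes of 1.2 were called at 0.66X, and smaller changes were not simulated.

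The same relation was then followed in PCR-variable, where cycles were adapted to each library and cultures and sequencing differed too. Among called peaks with at least 50 reads on average and the same sign in every isolation, 2:117509661-117509945 again fell most, from 82.7 ± 12.7 CPM at 0.2X through 21.9 ± 1.47 at 1X to 8.40 ± 0.0963 at 5X in the low run (n = 3, slope −0.74, SE 0.033, edgeR adjusted p = 4e-50). The peak at 2:186603486-186603999 fell from 51.1 ± 4.76 to 9.73 ± 0.276 CPM (slope −0.51) and that at 6:2367243-2367462 from 23.03 ± 9.48 to 5.45 ± 0.950 CPM (slope −0.46). The largest rises by this rule were at 2:136776925-136777299 (2.52 ± 1.37 to 10.7 ± 0.469 CPM, slope 0.35), 14:34009093-34009534 (6.34 ± 1.96 to 13.3 ± 2.25 CPM, slope 0.35) and 10:97579363-97580457 (3.12 ± 1.54 to 16.1 ± 2.87 CPM, slope 0.34). Below 50 reads on average, 4 called peaks had a steeper fall and 38 a steeper rise, with a slope of −1.02 (SE 0.050, mean of 48.0 reads) at 1:77436816-77437201 and −0.95 (SE 0.058, mean of 36.2 reads) at 9:34999061-34999393. Of 65481 peaks tested, 12173 changed, 5383 upwards and 6790 downwards, a majority that scaling to total reads turned to 6673 upwards and 6120 downwards. Of the 8183 with a mean of at least 50 reads, 7962 had the same sign in all 3 isolations.

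With the number of PCR cycles, which fell with Tn5, in the same fit, 13 peaks were called, all falling, and of the 6 named peaks 2:117509661-117509945 alone passed the threshold. Thinned libraries gave 4780 calls among 46684 peaks tested, the fit without the 5X libraries 3555, the sum of both runs 19059, and leaving out 1 isolation 6762 to 7484. Between the experiments, 50719 master peaks were matched and 50406 of these tested in both. Their slopes correlated with r = 0.561 (rho = 0.519) across peaks, which are not independent replicates. Peaks called in both numbered 5245, against 3044.4 for independent lists of these sizes, and 5094 of them (97.12%) had the same sign, 1785 rising and 3309 falling. The remaining 151 had opposite signs.

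The change with Tn5 was compared between classes of master peaks. In PCR-constant the quartile of widest peaks had a median slope lower than that of the narrowest by 0.047 ± 0.028 (mean ± SD over 6 isolations; class medians −0.020 and 0.027 log2 per doubling), with the widest class lower in 6 of 6 isolations (two-sided exact permutation p = 0.03125). The difference was −0.070 in isolations 1 to 3 and −0.024 in isolations 4 to 6, and −0.070 with slopes of log2 CPM. Within each quartile of mean CPM the widest class was also lower in 6 of 6 isolations, with differences from −0.097 to −0.074. Among the widest peaks 24.16% fell and 9.79% rose, and among the narrowest 6.87% fell and 12.2% rose. The widest had a median of 21.4 CPM and the narrowest 3.12, so a change was easier to call among the widest. In PCR-variable the widest quartile lay above the narrowest by 0.025 ± 0.0034 in 3 of 3 isolations (exact permutation p = 0.25), but by 0.0014 with slopes of log2 CPM and 0.0025 with loess offsets. Within quartiles of mean CPM, from the lowest to the highest, it was −0.039, −0.028, 0.0017 and 0.014, with the widest class higher in 0, 0, 2 and 3 of 3 isolations, so the direction turned in the lower quartiles. The slopes of this contrast differed by 0.072 between the experiments (two-sided exact permutation p = 0.0119 over 84 splits, the smallest possible, and 0.107 adjusted over 9 such tests).

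**Figure D3:**
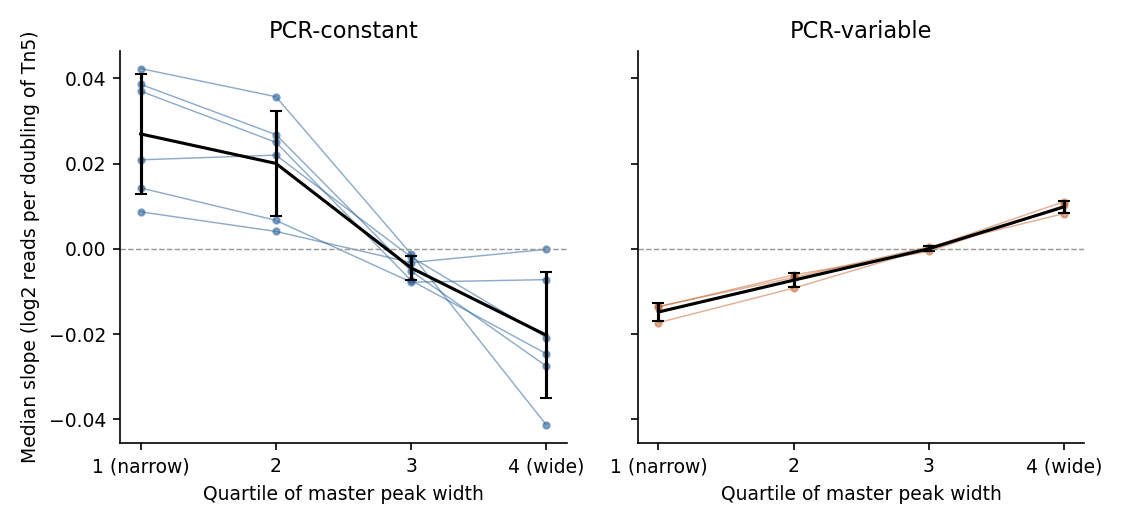
Median slope of master peaks in quartiles of width, in log2 reads per doubling of Tn5, with colored points and lines for each isolation and black lines and bars for the mean ± SD. In PCR-constant the class means went from 0.027 in the narrowest to −0.020 in the widest quartile, and in PCR-variable from −0.015 to 0.0099.

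The quartiles of highest and lowest mean CPM differed by 0.014 ± 0.033 in PCR-constant, within the spread between isolations (higher in 3 of 6, two-sided exact permutation p = 0.375). The difference was −0.015 in isolations 1 to 3, 0.043 in isolations 4 to 6 and −0.022 with slopes of log2 CPM. In PCR-variable it was 0.039 ± 0.0033 in 3 of 3 isolations (exact permutation p = 0.25) and 0.0049 with slopes of log2 CPM. Within each quartile of width the highest class lay above the lowest in 6 of 6 isolations of PCR-constant, by 0.052 to 0.095, and in 3 of 3 isolations of PCR-variable, by 0.026 to 0.079. With slopes of log2 CPM these contrasts were 0.024 to 0.060 in PCR-constant, positive in 3, 6, 6 and 5 of 6 isolations from the narrowest to the widest quartile, and −0.0076 to 0.035 in PCR-variable.

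The same PCR-variable libraries were compared between the high and the low cluster density run, in which every library was sequenced again. The narrow peaks at 9:34999061-34999393 (9.48 ± 9.84 CPM in the low and 22.9 ± 30.2 in the high run) and 1:77436816-77437201 (13.6 ± 16.7 and 27.2 ± 35.8 CPM) were higher in the high run by 1.15 and 0.91 log2 (edgeR adjusted p = 4.3e-33 and 3.8e-28) in all 20 libraries. DESeq2 gave 1.16 at the first of these without passing the threshold. It left 46963 of 63745 peaks without an adjusted p in this comparison, so not passing need not mean that a test failed. The peak at 2:208029896-208031739 was higher by 0.075 (edgeR adjusted p = 0.046) and missed the threshold with DESeq2, with no filter, after thinning, with isolation as the block and without each isolation in turn. The peaks at 2:148777807-148779188 (57.5 ± 3.95 and 48.4 ± 5.51 CPM, −0.26), 11:88034319-88035292 (−0.18) and 18:59853894-59855556 (−0.17) were lower. Of 63745 peaks tested, 1193 differed, 343 higher and 850 lower. Of the 1126 with a mean of at least 50 reads, 11 had the same sign in all 20 libraries. The share of higher calls was 28.75% with TMM factors and 39.37% with loess offsets.

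Thinning to the smallest total gave 42 calls among 35247 peaks tested, isolation in place of library as the block gave 82, and leaving out 1 isolation gave 411 to 473. Log2 reads in master peaks were higher in the high run by 0.27 in 20 of 20 libraries (two-sided exact permutation p = 1.907e-06). The top 10% share was lower in the high run in 20 of 20, with a mean difference of −0.137 points (exact permutation p = 1.907e-06). That top 10% was chosen by mean CPM in the low run, which favors a lower share in the high run. The test therefore cannot show an effect of the run on this share. The log2 number of peaks differed by 0.048 ± 0.18 (higher in 11 of 20 libraries, two-sided exact permutation p = 0.239), with means of −0.099, 0.12 and 0.13 in isolations 1, 2 and 3. In isolation 1 the 0.2X library stood apart at −0.50 (47191 peaks in the low and 33274 in the high run). Its other libraries lay between −0.15 and 0.17. Without isolation 1 the difference was 0.13, and for peaks with −log10 q of at least 5 it was 0.21, higher in 20 of 20 libraries (exact permutation p = 1.907e-06). These permutations take each library as a unit, although libraries of 1 isolation share a culture, and an exact sign-flip test over the 3 isolations could not give a p under 0.25.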

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

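The comparisons of slopes between the experiments, other than that of the number of peaks, and the search for sites outside the master peaks were tests chosen only after the slopes had been seen. Among 6 PCR-constant values of one kind, per concentration or as slopes of the isolations, 1 value stood apart from the other 5 in 2 of 48 groups, where chance alone gives 2.4. The 0.66X library of isolation 4 had 4356124 reads in master peaks, against 2595215 to 3178970 in the other 5. The 2X library of isolation 5 had a median fold enrichment of 5.60, against 4.73 to 4.97 in the other 5.

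Of 9 slopes compared between the experiments, 2 differed at an unadjusted p under 0.05 and 0 after adjustment. The slope of the median peak width was higher by 18.0 bp per doubling in PCR-variable (18.4 ± 5.69, n = 3) than in PCR-constant (0.417 ± 8.49, n = 6; two-sided exact permutation p = 0.0238, adjusted 0.107). The contrast of the widest and narrowest quartile was higher by 0.0719 in PCR-variable (0.025 ± 0.0034, n = 3) than in PCR-constant (−0.047 ± 0.028, n = 6; two-sided exact permutation p = 0.0119, adjusted 0.107), and by 0.0709 (exact permutation p = 0.0238) with slopes of log2 CPM.

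The peak lists also held sites that no master peak covers, 34 of them in every list and 641 in at least 50% of the lists. The 4 with the highest median fold enrichment, chosen after their values were seen, were each called in 82 of 82 lists. They were 8:100508002-100508281 (median fold 22.2), 17:22020593-22021061 (20.9), 1:569769-570060 (17.6) and 1:567445-567712 (15.9). Why the master peaks leave such sites out is not given in the sources used here. Whether they mark accessible chromatin was not tested, and a high fold enrichment does not show it.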

How the results depend on the processing

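The tests on isolations 1 to 3 and 4 to 6 alone, without the library with the fewest reads, with slopes of log2 CPM, with a block in the high run and of the depth estimate without 1 isolation were chosen only after the results were seen. Of 142 planned values of comparisons 115 kept their direction and side of the threshold or lay within 1.5 times, and of 47 added ones 37. For named peaks these were 446 of 466 and 100 of 113. A value that counted as kept could still differ in size. Sign-flip tests over the 3 PCR-variable isolations could not pass 0.05, so those values could only fail by a change of sign. At 0.66X every setting called 0 peaks. The PCR-variable slope of median fold enrichment counted as kept at 0.0111 with −log10 q of at least 5, against 0.182 in the main setting. Fewer calls came from fewer peaks or reads for the PCR-constant slope with at least 50 reads on average (10076), and from thinning for that slope (5985), 0.2X (172), 5X (2758), the PCR-variable slope (4780) and the runs (42). Without the 5X libraries the PCR-constant slope gave 8491 and the PCR-variable slope 3555, and without the 0.2X libraries 13962 and 10235. Without 1 isolation the PCR-variable slope gave 6762 to 7484 and the runs 411 to 473. Isolations 1 to 3 alone gave 6824 for the PCR-constant slope, 39 at 0.2X, 0 at 1.5X and 1130 at 5X, and isolations 4 to 6 alone 191 at 0.2X, 0 at 1.5X and 2599 at 5X (edgeR, with 2860 and 4386 peaks at a raw p under 0.05 at 1.5X; DESeq2 called 1 there over all isolations). The sum of both runs, with more reads, gave 19059 for the PCR-variable slope. With PCR cycles, which follow Tn5, as a covariate it gave 13. At 0.2X DESeq2 called 1114 and left 34390 peaks without an adjusted p, and loess offsets gave 338. The cause of these differences was not tested.

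The replicate number as a block gave 19298 calls for the PCR-constant slope, 641 at 0.2X, 6044 at 5X and 12205 for the PCR-variable slope, and 82 for the runs in place of the library block, whose pairing it drops. It moved no other count by over 1.5 times. The slope of the median peak width in PCR-constant was −18.9 (exact permutation p = 0.03125) with −log10 q of at least 5, −3.91 without the 0.2X libraries and −5.53 in isolations 4 to 6. That of the top 10% share was −0.557 (exact permutation p = 0.125) without the 5X and −0.439 (p = 0.0938) without the 0.2X libraries. The difference of log2 peaks between runs was 0.21 with the stricter q and 0.0080 to 0.13 without 1 isolation. That of the slopes of log2 peaks between experiments was −0.053 to 0.0017 without 1 isolation. The mean CPM contrast in PCR-constant was −0.022 with slopes of log2 CPM and −0.015 in isolations 1 to 3. Within quartiles of PCR-variable peaks, slopes of log2 CPM turned the width contrast to −0.0042 in the third quartile of mean CPM and the mean CPM contrast to −0.0076 in the narrowest. The percent of the slope of log2 peaks left once depth was taken out by both runs was −4.9 to 92.0 without 1 isolation. The correlation of slopes was 0.570 with the high run, and 12:6960400-6962337 had a slope of 0.044 with loess offsets. The cause was not tested for these either. The share of reads near transcription start sites, the class of peaks near them and the gene lists were not run. Depth limits the number of calls for the slopes, 0.2X, 5X and the runs, which fell on thinning.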

Other observations

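The classes by number of neighbours and by chromosome, the estimate of depth effects from both runs of a library, the correlation over peaks called in PCR-variable and the comparisons of the gain of reads between runs and of the 0.2X run pairs with counting noise were tests chosen only after the result was seen. Master peaks were grouped by the number of other master peaks within 50 kb. Isolated peaks, with 0 neighbours, lost relative reads as Tn5 increased in PCR-constant, where 39.78% of 4580 fell and 1.7% rose (median slope −0.11 ± 0.030 log2 per doubling, mean ± SD over 6 isolations). Crowded peaks, with over 10 neighbours, went the other way, and 27.92% of 2224 rose and 3.64% fell (median slope 0.047 ± 0.011). The classes differed by 0.152 ± 0.041, in 6 of 6 isolations (two-sided exact permutation p = 0.03125, the smallest possible), by 0.115 in isolations 1 to 3 and by 0.190 in isolations 4 to 6. In PCR-variable 27.95% of 5055 isolated peaks fell and 20.59% of 2253 crowded peaks rose. Within each quartile of mean CPM and of width the difference was positive in all isolations of both experiments, between 0.094 and 0.192 in PCR-constant.

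Chromosomes differed in the same terms. On chromosome 4, 26.77% of master peaks fell and 5.32% rose in PCR-constant (median slope −0.048 ± 0.022, below 0 in 6 of 6 isolations), and chromosomes 8 (−0.018 ± 0.013) and 5 (−0.017 ± 0.0093) came next. On chromosome 22, 25.9% rose and 2.38% fell (median slope 0.051 ± 0.018, above 0 in 6 of 6 isolations), followed by chromosomes 21 (0.042 ± 0.0058), 17 (0.040 ± 0.018) and 19 (0.035 ± 0.026). Over the 22 chromosomes the median slopes of both experiments correlated with r = 0.96 (rho = 0.965), across chromosomes, which are not independent replicates.

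After every PCR-constant library was thinned to the smallest total, the fitted median slopes of crowded and isolated peaks differed by 0.121, against 0.135 before on the same 33530 peaks, so 89.7% was left, which argues against library depth as the whole cause. The difference was 0.146 with loess offsets, above 0 in 6 of 6 isolations, which argues against a trend with peak abundance. It was 0.159 ± 0.010 in PCR-variable, above 0 in 3 of 3 isolations (exact permutation p = 0.25, the smallest possible), which argues against the fixed 16 PCR cycles. With slopes of log2 CPM it was 0.123 and 0.135. GC content and the sequence preference of Tn5 were not tested and stay open, and no biological explanation was tested.

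More peaks were called at higher Tn5, where libraries also had more reads in master peaks. Depth is measured here by these reads and not by all reads sequenced. Between PCR-constant libraries at the same Tn5 concentration, log2 peaks rose by 0.473 per unit of log2 reads, and taking this out left 9.5% of the slope of log2 peaks (0.28 ± 0.092 before and 0.026 ± 0.033 after, above 0 in 5 of 6 isolations, two-sided exact permutation p = 0.0625). The same library sequenced in both runs gave 8.4% left for peaks with −log10 q of at least 5 (0.53 before and 0.045 after, and 4.8 to 12.9% without 1 isolation), but 56.1% for all peaks (0.25 before and 0.14 after, above 0 in 3 of 3 isolations). The value for all peaks rested on isolation 1, where the high run gave fewer peaks than the low run (−0.099 log2): −4.9% was left without it, and 92.0% and 89.1% without isolation 2 or 3. Within isolation 1 the 0.2X library had by far the largest fall (−0.50, against −0.15 to 0.17 in its other libraries). The estimate without that library alone was not made. Library depth in this sense could therefore account for most of the rise by the first estimate and, for peaks of stricter q, by the second. For all peaks depth and the amount of Tn5 cannot be told apart by the second, since 1 isolation decides it. Reads in master peaks also depend on the share of all reads that falls in peaks, which was not measured. An effect of Tn5 on that share was therefore not separated from depth. No biological explanation was tested.

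Between the low and the high run the counts of the 0.2X PCR-variable libraries differed by less than counting noise, with a chi-square per degree of freedom of 0.673 ± 0.136 (0.565 to 0.826, n = 3), against 1.692 ± 0.091 at 1X and 1.895 ± 0.001 at 5X (n = 3 each). Thinning the 1X and 5X libraries to the reads of the 0.2X library of the same isolation brought their values to between 1.098 and 1.247. Thinning draws reads singly, which brings such a value towards 1 whatever raised it. It therefore cannot show whether lower depth accounts for part of the difference. Fewer independent reads do not bring the value below 1, and the highest value at 0.2X was 0.826 (counting SD 0.0072). This argues against lower depth as the whole cause. Log2 reads rose from the low to the high run by 0.14 ± 0.057 at 0.2X and by 0.318 ± 0.039 at 5X, a difference of 0.179 ± 0.082 in 3 of 3 isolations (two-sided exact permutation p = 0.25, the smallest possible). A candidate explanation is that both runs read the same molecules again in a library with few molecules, after removal of duplicates. How duplicates were treated is not given in the sources used here, and no biological explanation was tested.

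The narrow peaks at 1:77436834-77437201 and 9:34999075-34999391, chosen after their values were seen, fell in PCR-constant from 73.5 ± 69.4 and 43.9 ± 44.9 CPM at 0.2X to 1.66 ± 0.809 and 1.35 ± 0.706 at 5X (mean ± SD, n = 6). Their slopes of log2 CPM were −1.03 ± 0.14 and −0.95 ± 0.13, below 0 in 6 of 6 isolations. In PCR-variable the slopes at the matching peaks were −1.02 and −1.01 in the low run and −1.04 and −0.93 in the high run, below 0 in 3 of 3 isolations, although their levels differed between the runs (50.4 and 30.6 CPM in the low and 105.1 and 84.9 in the high run at 0.2X). The fitted slopes of both experiments correlated with r = 0.561 over all 50406 matched peaks and with r = 0.78 over the 10292 called in PCR-variable, of which 85.65% had the same sign in PCR-constant. Over the 5245 called in both, a selection that favors strong slopes, r was 0.9134. These values argue against PCR cycle number as the whole cause of the slopes in PCR-variable, since the cycles did not differ in PCR-constant.

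Other splits of the libraries were fitted in the same way. The real assignment called as many peaks in 1 of 40 splits, itself, for the PCR-constant slope (18454 peaks, highest other split 2) and the PCR-variable slope (12173, highest other 0). The same held for 1 of 32 splits at 0.2X (595, highest other 21), 1.5X (1, highest other 0) and 5X (5475, highest other 247), and for 1 of 22 splits of the runs (1193, highest other 3). For the slopes, 0.2X, 5X and the runs the real count lay far above every other split, which argues against chance. With 22 to 40 splits the test cannot exclude it. The count at 1.5X is a single peak, which isolations 1 to 3 and 4 to 6 alone did not call (edgeR adjusted p = 0.59 and 0.055). A count of 1 against 0 does not exclude chance there. At 0.66X all 32 splits, the real one included, called 0 peaks with edgeR (2216 at a raw p under 0.05 in the real one, and 0 with DESeq2), and as no split can call fewer, this test decides nothing there.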
